A study of Homo sapiens with 18 samples.

How the data were processed

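RNA abundance was measured in 18 samples of human skin on Affymetrix HG-U133 Plus 2.0 arrays, a short-oligonucleotide platform that reads each transcript with 1 or more probe sets near its 3 prime end. The samples were 5 common nevi, 7 dysplastic nevi and 6 samples of normal skin, grouped by the tissue label of each sample. Replicate numbers within a group follow the order of deposit and pair no samples. Per the labels, both nevus types were taken as slices through the full thickness of the tissue, whereas normal skin was taken as bulk punch biopsies. RNA was extracted with an RNeasy kit, amplified by the Affymetrix double amplification protocol and labelled with biotin. Nothing in the sources used here says whether any samples came from the same donor, so p-values measure the spread between these samples.

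The values are log2 expression values per probe set, background-corrected, normalized and summarised by the authors with GCRMA per the submitters' processing notes. Its version, its settings and which arrays were processed together are not given in the sources used here. The deposited log2 values ran from 2.20 to 16.4 and shared a floor, with 34.9% of them within 0.01 of it. At that floor a value is a ceiling on the signal rather than a level, so a difference is given as "at least" where 1 group lay below log2 3 on every array and the other above it on every array. Where arrays of both groups lay near the floor, the fitted difference is neither a size nor a bound, and levels are given instead. Where some arrays of the lower group alone lay there, the difference is a low estimate. The number of arrays limits the precision of every value. No 2 arrays were identical, and correlations between arrays ran from 0.858 to 0.967.

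Of 54675 probe sets, 62 were controls, 41091 had 1 gene symbol in the platform annotation, 1801 had several and 11721 had none. Symbols were compared with the RefSeq gene table of GRCh38.p14, and 0 needed updating. Each of 19775 genes was represented by the probe set with the highest mean among those with 1 symbol. A gene was tested if it exceeded log2 3 on at least 5 arrays, which left 13229 genes. No coordinates are given because the files name no genome build. Levels of 16 genes, on the Y chromosome or encoding the RNAs of X inactivation, were left out of what is printed, and other X-linked genes were kept.

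The groups were compared with limma 3.58.1 in R 4.3.3. All 18 arrays entered 1 linear fit with 3 group means and empirical Bayes variances (15 residual degrees of freedom, 2.58 prior). The Benjamini-Hochberg adjustment was made within each comparison, and a gene was called at an adjusted p below 0.05. Fold changes are differences of log2 means with their standard errors (SE), and levels are means with standard deviations (SD). The genes named were set by rule before the data were examined: in each direction, the 12 genes (10 against normal skin) with the largest difference among those called, filled up by the lowest p where fewer were called. For each gene list, the 3 members with the lowest p could be named as well.

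Before the data were examined, 26 gene lists were fixed with 315 different genes, of which 247 were tested, 35 lay below the filter and 33 had no probe set of that symbol alone. They covered melanocyte lineage and pigment genes, ERK pathway output, growth arrest and senescence-associated genes, proliferation, and melanoma-associated antigens and invasion genes. For the skin they covered basal keratinocyte, terminal epidermal differentiation, activated keratinocyte and antimicrobial, inner root sheath, hair cortex and cuticle, outer root sheath and bulge, sebaceous gland and eccrine sweat gland genes. The others were dermal fibroblast and matrix, adipocyte, smooth muscle, endothelium, T cell, B and plasma cell, macrophage and dendritic cell, mast cell, interferon response, T helper cytokine, Schwann cell and nerve, immediate early and red blood cell genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. They were also tested with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. Members were also adjusted over the list alone.

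RNA quality was read from the ACTB and GAPDH control probe sets as the mean of the 3 prime minus 5 prime log2 signals, compared by two-sided exact permutation tests. The fit was tested on simulated data in which 50 genes were changed at each of 4 sizes. For dysplastic against common nevi it recovered 40% of changes of 1 on the log2 scale and 86% of changes of 2. For common nevi against normal skin these shares were 32% and 80%, and for dysplastic nevi against normal skin 52% and 88%. Unchanged genes made up 4.82%, 11.0% and 1.74% of the calls in these 3 simulations. The simulated noise was normal, independent between genes and of the same spread in all groups, and no floor was applied. These shares may therefore not hold for genes near the floor or where the groups vary unequally. Alternatives fixed beforehand covered the filter, the choice of probe set, quantile normalization, centring, array weights, fitting only the groups compared, a looser threshold, the RNA quality ratio as a covariate, the 2 common nevi titled in another way, and every array left out in turn. Added after the data were examined were the ranges of sample numbers in the titles, used as a block or compared within a range. A fit without common nevus replicates 1, 2 and 4 was added then too, and no stated measure set these 3 apart. Replicate 1 had the highest median correlation with its own group among the common nevi (0.927). That fit keeps replicates 3 and 5, of which replicate 3 correlated less with common nevi than with the other groups. Lower numbers were carried by 1 common nevus, 5 dysplastic nevi and 5 normal skin samples, and higher numbers by 2 common and 2 dysplastic nevi. The titles of 2 common nevi and of 1 normal skin sample were built in other ways, and each kind formed its own level of the block. With the block those arrays therefore informed no difference between groups. The 5 normal skin titles of lower numbers carried a suffix that no nevus title had, but shared a level with the nevi of lower numbers. Comparisons with normal skin, with the block or within the lower numbers, thus did not hold the form of the title constant. No normal skin sample carried a higher number. The 2 common nevi of higher numbers thus entered the blocked comparison with normal skin only through the dysplastic nevi, and 1 common nevus entered it directly. Whether these ranges mark separate collections is not given in the sources used here. Figures were drawn with matplotlib.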

Results

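Genome-wide RNA abundance was profiled in melanocytic nevi, benign growths of pigment cells in the skin, and in normal skin. The 18 arrays comprised 5 common nevi, 7 dysplastic nevi, which are nevi with atypical features, and 6 normal skin samples. On each array between 49.9% and 51.0% of all probe sets exceeded log2 3. The first principal component held 23.6% of the variance and separated most of the normal skin arrays from the nevi. Values below are log2 expression, and differences are log2 fold changes with the first-named group minus the other (n = 5 common nevi, 7 dysplastic nevi and 6 normal skin samples throughout).

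Dysplastic nevi were compared with common nevi first, since the study's title names this contrast. Camera called the activated keratinocyte, inner root sheath and dermal matrix lists higher in dysplastic nevi, while the melanocyte and outer root sheath lists were not called and no member of any list passed over all genes. The activated keratinocyte and antimicrobial list, genes that epidermis turns on when it is inflamed or wounded, had a median difference of 2.59 (camera adjusted p = 1.29e-09; adjusted p = 0.146 with an estimated correlation). Of its 13 measured members 0 passed over all genes tested, and 10 were higher when adjusted over the list alone. LCE3D, a cornified envelope protein, differed by 4.75 (SE 1.23, adjusted p = 0.201) and RNASE7, an antimicrobial ribonuclease, by 2.14 (SE 0.55, adjusted p = 0.201). The inner root sheath list, keratins and trichohyalin of the growing hair follicle, had a median difference of 5.39 (camera adjusted p = 1.18e-07; adjusted p = 0.146 with an estimated correlation), with 0 of 7 members passing over all genes and 6 adjusted over the list alone. Its keratin KRT25 lay between 9.51 and 11.6 on 5 dysplastic nevus arrays and at most at 2.27, next to the floor, on the other 2 and on all 5 common nevus arrays (adjusted p = 0.191). KRT71 lay between 8.11 and 11.1 on the same 5 arrays and at the floor on the others of both groups (adjusted p = 0.191), so the list median is a distance to values near the floor and not the size of a change. TCHH, which encodes trichohyalin, exceeded log2 5 on 5 of 7 dysplastic nevus arrays and on 0 of 5 common nevus and 0 of 6 normal skin arrays.

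Dermal fibroblast and matrix genes were higher in dysplastic than in common nevi with a median difference of 1.04 (camera adjusted p = 7.42e-10; adjusted p = 0.146 with an estimated correlation). None of its 15 members passed over all genes and 12 were higher when adjusted over the list alone, among them the collagens COL3A1 (1.04, SE 0.25), COL1A2 (1.35, SE 0.33) and COL1A1 (1.29, SE 0.33). The melanocyte lineage and pigment list had a median of -0.091 over 18 members (camera adjusted p = 0.981), and its mean of 0.060 had the opposite sign. When adjusted over the list alone, 3 of its members were higher, MC1R (1.56, SE 0.43), the receptor for melanocyte-stimulating hormone, OCA2 (1.61, SE 0.45), which controls melanosome pH, and PMEL (1.61, SE 0.53), the fibril protein of melanosomes. Without the 2 common nevi titled in another way these differences were 0.87, 1.05 and 0.50, and those of COL3A1, COL1A2 and COL1A1 were 0.89, 0.94 and 0.76. PMEL averaged 9.69 on these 2 arrays and 12.5 on the other 3 common nevi.

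Of the 13229 genes, limma called 1 between the nevus types. This was C2orf49-DT, a divergent non-coding transcript, which averaged 3.01 ± 0.13 (SD) in dysplastic and 5.05 ± 0.95 in common nevi, a difference of -2.04 (SE 0.29, adjusted p = 0.0197). Its call was kept under 22 of 32 alternatives, with adjusted p from 0.00119 to 0.949. At an unadjusted p below 0.05 there were 1483 genes, 955 higher and 528 lower. Among the 12 genes with the lowest p on the higher side, none of which passed, WIPI1, an autophagy protein, differed by 1.25 (SE 0.21, adjusted p = 0.0807) and GRHL3, a transcription factor of the epidermal barrier, by 2.16 (SE 0.42, adjusted p = 0.187). EPPK1, a cytoskeletal linker of epithelia, differed by 1.30 and IGFBP5, a binding protein of insulin-like growth factors, by 1.01. The protein-remodelling ATPase VCP differed by 0.90, the actin-binding LASP1 by 0.59 and MCHR1, a peptide hormone receptor near the floor on part of the arrays of both groups, was higher (adjusted p = 0.191). PLEKHF1 (1.68), ZSWIM3 (1.68), MRPL4 (1.09), PI4K2A (1.28) and DUSP3 (0.73) completed that set, and 1 of 3 probe sets of PI4K2A had the opposite sign. On the lower side, NUDT9, an ADP-ribose hydrolase, differed by -0.76 (SE 0.13, adjusted p = 0.105), the mismatch repair gene PMS1 by -1.06 and TIMM8A, a mitochondrial import factor, by -1.47. HAUS5 (-0.99, with 1 of 3 probe sets of opposite sign), SMIM10L2A (-1.44), NUDT17 (-1.06), MIX23 (-2.03), CDCA7L (-0.94), LOC101927608 (-0.80) and SPEN-AS1 (-1.05) also failed the threshold, as did GUSBP5, which lay below log2 3 on part of the arrays of both groups (adjusted p = 0.191).

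Terminal epidermal differentiation genes had a median of 1.24 (adjusted p = 1.18e-07; adjusted p = 0.307 with an estimated correlation), which was 0.41 without common nevus replicate 4. Macrophage and dendritic cell genes had a median of 0.98 (adjusted p = 1.45e-05; adjusted p = 0.25 with an estimated correlation), with CSF1R, the macrophage colony-stimulating factor receptor, at 1.69 (SE 0.48). Mast cell genes had a median of 1.22 (adjusted p = 0.00358; adjusted p = 0.25 with an estimated correlation). It turned negative within the lower title numbers (-0.33, with 1 common nevus) and without common nevus replicates 1, 2 and 4. The T cell median was 0.77 (adjusted p = 0.0113; adjusted p = 0.480 with an estimated correlation) and the immediate early median 0.62 (adjusted p = 0.0113; adjusted p = 0.505 with an estimated correlation). Growth arrest genes, among which IGFBP5 had the lowest p, had a median of 0.37 (adjusted p = 0.0205; adjusted p = 0.146 with an estimated correlation) and all 8 were above 0. Basal keratinocyte genes had a median of 0.32 (adjusted p = 0.0183; adjusted p = 0.354 with an estimated correlation). The hair cortex median over the 5 members that passed the filter was 0.62 (adjusted p = 0.0176; adjusted p = 0.25 with an estimated correlation) and the eccrine sweat gland median 1.33 (adjusted p = 0.0176; adjusted p = 0.584 with an estimated correlation). With no filter the hair cortex median was 1.65, where the members added lay below log2 3 on every common nevus array. Without common nevus replicate 4 the eccrine median was 0.13 (adjusted p = 0.967). When adjusted over the list alone, members were higher in the terminal differentiation list (3), mast cell list (3), basal keratinocyte list (2), and in the macrophage, growth arrest and hair cortex lists (1 each), and 0 in the T cell, immediate early and eccrine lists. Over all genes 0 members of any list passed. With fry, the activated keratinocyte (adjusted p = 0.0241), inner root sheath (0.0214), matrix (0.0214) and growth arrest (0.00287) calls held. The terminal differentiation (0.113), macrophage (0.0909), mast cell (0.103), T cell (0.247), immediate early (0.257), basal keratinocyte (0.103), hair cortex (0.0909) and eccrine (0.359) calls did not.

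Without common nevus replicate 1, camera no longer called the basal keratinocyte (median 0.21, adjusted p = 0.0869), T cell (0.59, adjusted p = 0.103), hair cortex (0.58, adjusted p = 0.0560) and growth arrest lists (0.36, adjusted p = 0.0513). Without common nevus replicate 2 it no longer called the basal keratinocyte (0.17, adjusted p = 0.125), T cell (0.63, adjusted p = 0.140) and immediate early lists (0.16, adjusted p = 0.225), and the last was also lost without dysplastic nevus replicate 1 (0.41, adjusted p = 0.0533). The proliferation list was not called in this comparison (median 0.40, adjusted p = 0.131). Nor were the T helper cytokine (1.01, adjusted p = 0.0636), Schwann cell and nerve (-0.23, adjusted p = 0.0636), sebaceous gland (0.78, adjusted p = 0.157) and red blood cell lists (1.17, adjusted p = 0.297). The ERK pathway output list had a median of 0.0025 and a mean of -0.012 (adjusted p = 0.730), the interferon response list 0.078 and -0.067 (adjusted p = 0.860), and the outer root sheath list -0.25 and 0.25 (adjusted p = 0.644). Melanoma-associated (0.055), adipocyte (0.58), smooth muscle (0.17), endothelium (0.067) and B and plasma cell (-0.10) lists were not called either.

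**Figure D1:**
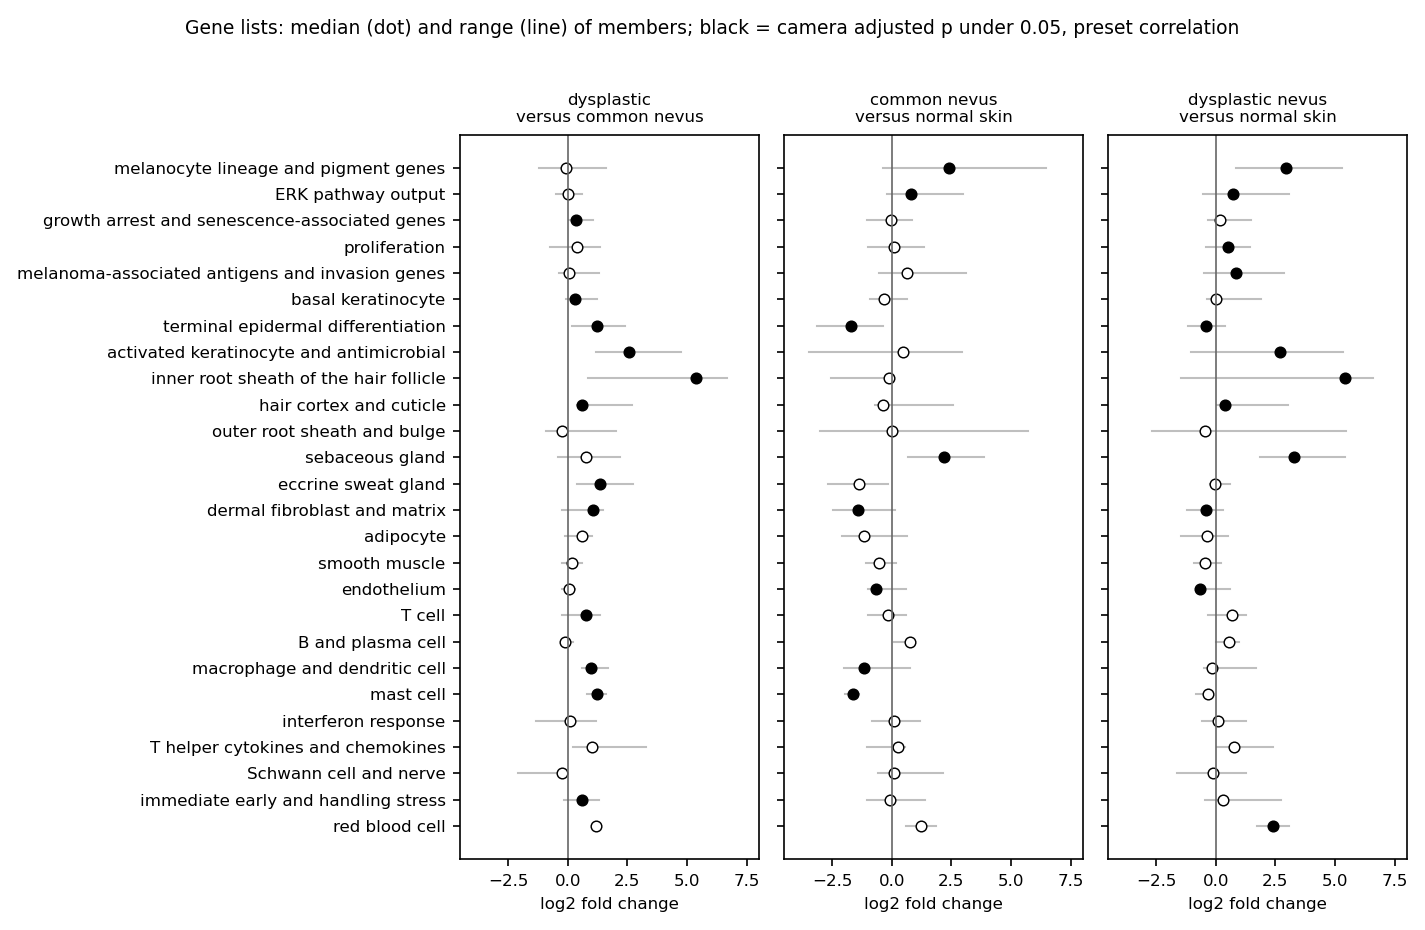
Each row is a gene list and each panel a comparison; dots mark the median log2 fold change over the members measured, lines run from the lowest to the highest member, and black dots mark lists that camera called at the preset correlation. The inner root sheath dot stands at 5.39 for dysplastic against common nevi, and the melanocyte dots stand at 2.42 and 2.93 in the comparisons with normal skin.

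The nevus samples also differed in the range of the sample numbers in their titles. With the range as a block, 2 genes were called between dysplastic and common nevi, 5 within the lower numbers (1 common and 5 dysplastic nevi) and 9 within the higher numbers (2 and 2). The activated keratinocyte median was 1.51 with the block, 1.5 within the lower numbers (adjusted p = 0.0934) and 1.75 within the higher numbers. The inner root sheath median was 4.51, 6.29 and 2.95 (adjusted p = 0.475 in the last) and the matrix median 0.54, 0.43 (adjusted p = 0.102 in the lower numbers) and 0.53. Terminal differentiation gave 1.13, 0.023 (adjusted p = 0.951 in the lower numbers) and 1.91. Without common nevus replicate 3, 68 genes were called, 50 higher and 18 lower, and without dysplastic nevus replicates 1, 2, 3 or 5 the count was 0. Without common nevus replicates 1, 2 and 4 together, which leaves replicates 3 and 5, the activated keratinocyte median was 1.05 and no longer called (adjusted p = 0.0880). The terminal differentiation median of 0.056 was not called either (adjusted p = 0.733), while inner root sheath (5.37) and matrix (0.64) stayed called. With the block, camera also no longer called the macrophage (0.41, adjusted p = 0.309), mast cell (0.48, adjusted p = 0.154), T cell (0.12, adjusted p = 0.936), immediate early (0.12, adjusted p = 0.971), growth arrest (0.38, adjusted p = 0.110), hair cortex (0.62, adjusted p = 0.475) and basal keratinocyte lists (-0.039, adjusted p = 0.971). The macrophage list was called neither within the lower (0.22, adjusted p = 0.622) nor within the higher numbers (0.57, adjusted p = 0.517), and not without the 3 common nevi (0.49, adjusted p = 0.325). The C2orf49-DT call ended with the block, within the lower numbers and without the 3 common nevi.

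In common nevi compared with normal skin, most genes of the melanocyte list rose, most of the matrix list fell and part of the cornification genes fell. Of 18 melanocyte lineage and pigment genes 13 rose and 0 fell, and 16 were higher when adjusted over the list alone. Their median was 2.42 (camera adjusted p = 1.69e-20), and this call held with an estimated correlation (adjusted p = 0.0465). TYR, the rate-limiting enzyme of melanin synthesis, rose by 4.05 (SE 0.33, adjusted p = 5.26e-06) and GPR143, a melanosome receptor, by 4.69 (SE 0.53, adjusted p = 1.88e-04). Of 15 dermal fibroblast and matrix genes 12 fell, and also 12 when adjusted over the list alone, with a median of -1.41 (camera adjusted p = 7.47e-10; adjusted p = 0.256 with an estimated correlation). The platelet-derived growth factor receptor PDGFRB fell by 2.19 (SE 0.37), FN1, fibronectin, by 1.94 (SE 0.36) and FBN1, fibrillin, by 2.41 (SE 0.49). Of 16 terminal epidermal differentiation genes 6 fell and 14 were lower when adjusted over the list alone, with a median of -1.69 (camera adjusted p = 2.68e-08; adjusted p = 0.458 with an estimated correlation), or -0.94 without common nevus replicate 4. The desmosomal cadherin DSG1 fell by 1.55 (SE 0.32), the transglutaminase TGM3 by 2.62 (SE 0.61) and the corneodesmosome gene CDSN by 2.68 (SE 0.71).

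In total 874 genes changed between common nevi and normal skin, 417 higher and 457 lower. The 10 largest rises were led by HHATL, a membrane-bound acyltransferase relative, at 10.9 ± 2.67 (SD) against 3.75 ± 1.09 in normal skin, a rise of 7.16 (SE 1.63, adjusted p = 0.0170). TRPM1, a cation channel of melanocytes, rose by 6.47 (SE 0.63, adjusted p = 2.60e-05). IGSF11, an adhesion molecule, rose by 5.73 (SE 0.71), the glutamate receptor subunit GRIA1 by at least 5.63 (SE 1.04) and the hexokinase relative HKDC1 by at least 5.65 (SE 1.14), since normal skin lay below log2 3 for both. CRTAC1 (5.47), GAPDHS (at least 5.25), the antisense transcript IDI2-AS1 (5.15) and the potassium channel KCNJ13 (4.94) also rose. LHX2, a homeobox gene of hair follicle stem cells, completed the set (adjusted p = 0.0398), at 9.20 or more on 4 of 5 common nevus arrays and 2.47 on replicate 2, against at most 2.72 on 5 of 6 normal skin arrays and 9.54 on replicate 4. Among the 10 largest falls, CILP, a cartilage matrix protein, fell by 4.42 (SE 0.78, adjusted p = 0.00433). PRG4, the lubricating proteoglycan lubricin, lay at the floor in all 5 common nevi and between 4.97 and 9.10 on 5 of 6 normal skin arrays, with replicate 4 at the floor (adjusted p = 0.00882). Ceruloplasmin, CP, fell by 4.01 (SE 0.88), the matricellular genes CCN5 and CCN4 fell by 3.70 (SE 0.58) and 3.32 (SE 0.94), and SVEP1, an extracellular adhesion protein, fell by 3.67 (SE 0.70). LVRN (-3.38), KPLCE (-3.35), IGSF10 (-3.26) and the zinc finger transcription factor ZIC1 (-3.29) also fell. With title number range as a block 19 of these 20 genes lost their call, all but TRPM1, within the lower numbers all 20 did, and without common nevus replicates 1, 2 and 4 it was 17. The fitted differences kept their sign, at 33.5% to 119% of their size with the block (median 70.1%, 17 of 20 at 50% or more), 10.6% to 178% within the lower numbers, where 1 common nevus remains (median 70.0%), and 56.4% to 135% without the 3 common nevi (median 90.7%). The smallest shares were those of HKDC1 with the block and CP within the lower numbers. Over the alternatives the fold change of CP ran from -4.93 to -0.42, that of KPLCE from -4.00 to -0.51 and that of CILP from -5.17 to -1.29. The calls of LHX2, CCN4, IGSF10, ZIC1 and KPLCE also ended when single arrays were left out and were kept under 16, 14, 18, 18 and 19 of 32 alternatives, with adjusted p up to 0.762, 0.355, 0.957, 0.608 and 0.999.

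ERK pathway output genes, the feedback targets of the growth factor cascade, were higher as a group in common nevi with a median of 0.83 (camera adjusted p = 0.00123; adjusted p = 0.256 with an estimated correlation). Of 12 members 3 rose and 5 were higher when adjusted over the list alone. ETV5 rose by 3.01 (SE 0.44, adjusted p = 0.00120), PHLDA1 by 1.36 (SE 0.32, adjusted p = 0.0188) and SPRY2 by 1.34 (SE 0.37, adjusted p = 0.0410). Sebaceous gland genes had a median of 2.2 (camera adjusted p = 0.00123; adjusted p = 0.628 with an estimated correlation), or 1.19 without common nevus replicate 4, and 1 of 12 rose, FAR2 by 3.86 (SE 0.96), which makes wax alcohols. Macrophage and dendritic cell genes had a median of -1.17 (camera adjusted p = 0.00304; adjusted p = 0.580 with an estimated correlation), with 1 of 12 falling and 3 lower when adjusted over the list alone. The complement gene C1QC fell by 2.0 (SE 0.56). Mast cell genes had a median of -1.62 (camera adjusted p = 0.00340; adjusted p = 0.458 with an estimated correlation), with 2 of 5 falling and 4 lower when adjusted over the list alone. The mast cell protease CPA3 fell by 1.38 (SE 0.40) and the histamine-forming enzyme HDC by 1.62 (SE 0.47). Endothelium genes had a median of -0.65 (camera adjusted p = 0.0313; adjusted p = 0.458 with an estimated correlation), with 1 of 7 falling, VWF by 0.95 (SE 0.23), and 3 lower when adjusted over the list alone. That call ended without common nevus replicate 2 (adjusted p = 0.0530) or 5 (0.0935) and without normal skin replicate 4 (0.05001), 5 (0.0524) or 6 (0.0633). The macrophage list was no longer called without the 2 common nevi titled in another way (-0.93, adjusted p = 0.0505), without common nevus replicates 1, 2 and 4 (-0.46, adjusted p = 0.354) or with title number range as a block (0.0020, adjusted p = 0.860). The mast cell call ended with the block (-0.87, adjusted p = 0.117) and without those 3 common nevi (-0.30, adjusted p = 0.326), and within the lower numbers the ERK (0.30, adjusted p = 0.414) and endothelium calls ended (-0.39, adjusted p = 0.215). With fry, the sebaceous (adjusted p = 0.168) and macrophage calls (0.0824) did not hold and the other 6 of this comparison did.

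Other lists were not called between common nevi and normal skin. MIA (3.11, SE 0.53) and CSPG4 (2.28, SE 0.64), a pair of melanoma-associated genes, rose in a list of 5 whose median was 0.62 (adjusted p = 0.0874), and the nucleotide synthesis gene TYMS rose by 1.37 in a proliferation list with a median of 0.12 (adjusted p = 0.386). IGFBP5 fell by 1.05 (SE 0.23) in a growth arrest list with a median of -0.013, and LEF1, a Wnt pathway transcription factor, rose by 2.59 (SE 0.35) in the hair cortex list, whose median was -0.37 and mean 0.18 (adjusted p = 0.744). KRT73 fell by 2.53 (SE 0.72) in an inner root sheath list with a median of -0.11 (adjusted p = 0.386). RNASE7 fell by 3.17 (SE 0.57) in the activated keratinocyte list, whose median was 0.48 and mean -0.047 (adjusted p = 0.787). The outer root sheath list had a median of -0.0055 and a mean of 0.31, the T helper cytokine list 0.26 and -0.17, and the immediate early list -0.076 and 0.023. Medians of the basal keratinocyte (-0.32), eccrine (-1.38), adipocyte (-1.15), smooth muscle (-0.55), T cell (-0.17), B and plasma cell (0.76), interferon (0.078), Schwann cell (0.084) and red blood cell (1.23) lists were not called. With title number range as a block, 8 genes were called between common nevi and normal skin, and within the lower numbers (1 common nevus and 5 normal skin samples) 5 were called. No normal skin sample carried a higher number, and the melanocyte median was 2.01 with the block and 2.01 within the lower numbers. The matrix median was -0.66 and -0.58, and the terminal differentiation median -1.10 and -0.17 (adjusted p = 0.449 in the last). Sliced tissue and nevus, and bulk biopsy and normal skin, coincided in every sample.

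**Figure D2:**
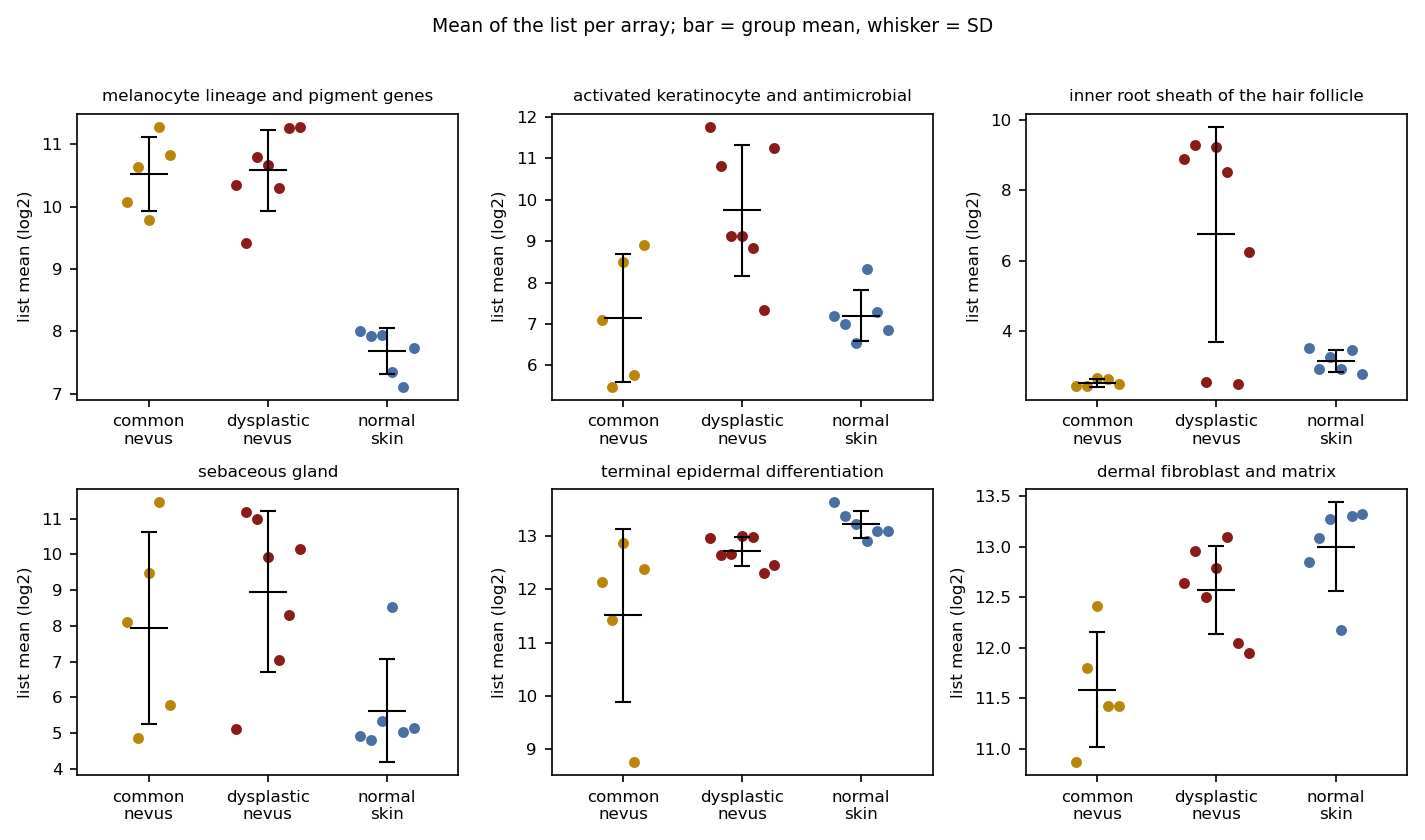
Points are arrays and show the mean log2 value over the members of a list, bars are group means and whiskers SD (5 common nevi, 7 dysplastic nevi, 6 normal skin samples). Inner root sheath genes separate 5 dysplastic nevus arrays from the other 2, and melanocyte genes are higher on all 12 nevus arrays than on the 6 normal skin arrays.

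In dysplastic nevi compared with normal skin, pigment cell genes and part of the keratinocyte and hair follicle genes rose. Of 18 melanocyte lineage and pigment genes 16 rose, 18 were higher when adjusted over the list alone, and the median was 2.93 (camera adjusted p = 5.20e-31; adjusted p = 0.00782 with an estimated correlation). TYR rose by 4.16 (SE 0.30, adjusted p = 8.99e-07), GPR143 by 5.12 (SE 0.49, adjusted p = 2.65e-05) and TRPM1 by 5.28 (SE 0.57, adjusted p = 8.62e-05). Of 13 activated keratinocyte and antimicrobial genes 2 rose, 8 were higher when adjusted over the list alone, and the median was 2.71 (camera adjusted p = 1.09e-05; adjusted p = 0.292 with an estimated correlation). S100A8, a calcium-binding alarmin, rose from 7.40 ± 1.56 (SD) to 12.7 ± 1.93, by 5.35 (SE 0.93, adjusted p = 0.00474), and the cornified envelope precursor SPRR1A rose by 4.17 (SE 0.98). Of 7 inner root sheath genes 4 rose, 5 were higher and 1 was lower when adjusted over the list alone, and the median was 5.40 (camera adjusted p = 0.00413; adjusted p = 0.408 with an estimated correlation). Those that rose were TCHH (adjusted p = 0.0485), KRT25 (0.0329), KRT71 (0.0328) and KRT27 (0.0312), which were measured on 5 of 7 dysplastic nevus arrays. On these TCHH lay between 8.89 and 13.3, KRT25 between 9.51 and 11.6, KRT71 between 8.11 and 11.1 and KRT27 between 8.25 and 10.9. In normal skin TCHH was at most 3.54, KRT25 at most 2.54 and the other 2 lay at the floor, as all 4 did on dysplastic nevus replicates 3 and 6, so the fitted differences and the list median give no size of change. The calls of KRT25, KRT71 and KRT27 were kept under 18, 18 and 19 of 32 alternatives, with adjusted p up to 0.0736, 0.0736 and 0.0723. The TCHH call was kept under 11 of them, with adjusted p from 0.00825 to 0.0961, and ended when any of several single arrays, dysplastic nevus replicates 1, 2, 4, 5 and 7 among them, was left out.

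In total 226 genes changed between dysplastic nevi and normal skin, 166 higher and 60 lower, a share of 73.5% higher. With arrays centred on their medians, 148 of 236 calls were higher, and with quantile normalization 158 of 236. Other large rises were those of the glycine-cleaving enzyme GLDC (5.28, SE 1.25), IGSF11 (4.94, SE 0.66) and GAPDHS (at least 4.88, SE 0.55), a glyceraldehyde phosphate dehydrogenase otherwise typical of sperm. Among the 10 largest falls, PRG4 (adjusted p = 0.00900), AGR3, an endoplasmic reticulum protein of secretory epithelia (adjusted p = 0.010), and the secreted glycoprotein gene STC2 (adjusted p = 0.00401) lay near the floor in dysplastic nevi, at most at 3.32, 2.50 and 2.71, and also on 1 normal skin array each. PCOLCE2, an enhancer of procollagen processing, fell by 3.07 (SE 0.65). The transcription factor SIM1 fell by 2.68 (SE 0.67), the Wnt inhibitor WIF1 by 2.67 (SE 0.59), the elastic fibre gene MFAP5 by 2.58 (SE 0.52) and the guanylate cyclase subunit GUCY1A2 by 2.51 (SE 0.47). The tight junction gene CLDN11 fell by 2.46 (SE 0.46) and the prostacyclin synthase PTGIS by 2.41 (SE 0.41). With title number range as a block 9 of the 20 named genes lost their call and within the lower numbers 13 did, while the fitted differences were 73.7% to 118% (median 91.6%) and 72.4% to 123% (median 91.3%) of their size. The calls of SIM1, GLDC, WIF1 and PCOLCE2 also ended when single arrays were left out and were kept under 15, 19, 22 and 27 of 32 alternatives, with adjusted p up to 0.165, 0.147, 0.129 and 0.140.

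ERK pathway output genes had a median of 0.72 in dysplastic nevi against normal skin (camera adjusted p = 5.00e-04; adjusted p = 0.268 with an estimated correlation). Of 12 members 2 rose, ETV5 by 3.06 (SE 0.40) and PHLDA1 by 1.37 (SE 0.29), and 7 were higher when adjusted over the list alone. Sebaceous gland genes had a median of 3.27 (camera adjusted p = 1.33e-07; adjusted p = 0.292 with an estimated correlation), with 0 of 12 passing over all genes and 11 higher when adjusted over the list alone. Proliferation genes had a median of 0.53 (camera adjusted p = 0.00650; adjusted p = 0.514 with an estimated correlation), and this call ended without dysplastic nevus replicate 1 (0.34, adjusted p = 0.0883). Melanoma-associated genes had a median of 0.85 (camera adjusted p = 0.0152; adjusted p = 0.292 with an estimated correlation), or 1.86 without normal skin replicate 3, and MIA rose by 2.88 (SE 0.49). The hair cortex list had a median of 0.40 (camera adjusted p = 0.0176; adjusted p = 0.292 with an estimated correlation), or 1.80 with no filter, with LEF1 rising by 3.01 (SE 0.32), and its call ended without dysplastic nevus replicate 1 (0.14, adjusted p = 0.0756). The red blood cell list of 2 haemoglobin genes had a median of 2.39 (camera adjusted p = 0.0400; adjusted p = 0.342 with an estimated correlation) and lost its call without any 1 of 7 arrays and with title number range as a block. Lower as groups were terminal epidermal differentiation (-0.40, camera adjusted p = 0.0184; adjusted p = 0.656 with an estimated correlation), dermal matrix (-0.39, camera adjusted p = 0.0152; adjusted p = 0.553 with an estimated correlation) and endothelium (-0.66, camera adjusted p = 0.00589; adjusted p = 0.292 with an estimated correlation), with 0 members passing over all genes and 1, 1 and 3 lower when adjusted over the list alone. With fry, the inner root sheath (adjusted p = 0.0514), matrix (0.289), terminal differentiation (0.479), proliferation (0.172) and red blood cell (0.0510) calls did not hold and the other 7 of this comparison did. The terminal differentiation call ended without normal skin replicate 1 (-0.36, adjusted p = 0.0591).

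Basal keratinocyte genes had a median of 0.0011 between dysplastic nevi and normal skin (adjusted p = 0.972), and 1 of 8 rose, the cadherin CDH3 by 1.88 (SE 0.33). The outer root sheath list had a median of -0.44 and a mean of 0.56, the eccrine list -0.041 and 0.081, and the macrophage list -0.17 and 0.042, none of them called. Growth arrest (0.16), adipocyte (-0.36), smooth muscle (-0.44), T cell (0.69), B and plasma cell (0.54), mast cell (-0.33), interferon (0.076), T helper cytokine (0.75), Schwann cell (-0.10) and immediate early (0.32) medians were not called either. With title number range as a block, 163 genes were called between dysplastic nevi and normal skin, and within the lower numbers (5 and 5 samples) 120. The melanocyte median was 2.46 with the block and 2.58 within the lower numbers, the activated keratinocyte median 2.89 and 2.86, and the inner root sheath median 6.06 and 6.36. Terminal differentiation (-0.10, adjusted p = 0.445, and -0.24, adjusted p = 0.130) and matrix genes (-0.15, adjusted p = 0.137, and -0.15, adjusted p = 0.127) were not called in these fits. Fitting only the 2 groups compared gave 410 genes, array weights 922 and the RNA quality covariate 432, and without normal skin replicate 5 or dysplastic nevus replicate 7 the count was 134 or 144.

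Both nevus types changed 158 genes the same way against normal skin, 116 higher and 42 lower, and 0 in opposite directions. This was 69.9% of the genes called in dysplastic and 18.1% of those called in common nevi, and TYR, TRPM1, GPR143, ETV5 and MIA were among those that rose in both. In 100 simulations that drew all arrays anew with no gene changed, the shared count was 0 on average and 0 at most. Few calls can arise where no gene changes, so this count does not measure what shared controls add to real calls. Independent lists of these sizes would share 5.23 higher and 2.07 lower genes. With the normal skin arrays divided into sets of 3, 1 for each nevus type, 22 to 34 genes were shared over the 20 divisions. Each comparison then had 3 controls rather than 6, and how much of the drop is lost precision was not tested. Across genes, which are not independent replicates, the fold changes correlated with r = 0.73, against 0.49 in the simulations, where the shared controls alone make the correlation. With divided controls r ran from 0.47 to 0.60. The fold changes of a divided comparison share no array, so noise that is independent between arrays would give no correlation there. Their covariance had a median of 0.29 over the divisions. With shared controls the covariance was 0.34 against 0.074 simulated, a difference of 0.27. Slicing against bulk biopsy is common to both nevus types, so neither r nor the covariance separates it from nevus. With title number range as a block 7 genes were shared, and within the lower numbers 1.

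**Figure D3:**
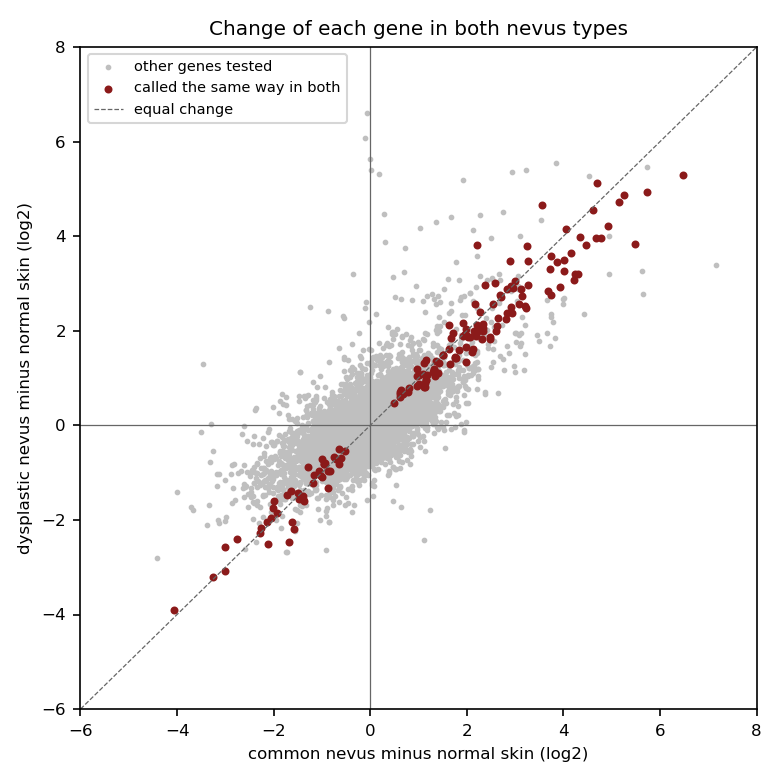
Each point is a gene tested, with its log2 fold change against normal skin in common nevi on the x axis and in dysplastic nevi on the y axis; dark points are the 158 genes called the same way in both, and the dashed line marks equal change. TRPM1 lies at 6.47 and 5.28, and TCHH lies near 0 on the x axis at -0.075 and at 6.60 on the y axis.

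The RNA quality ratio did not differ between groups beyond the spread between arrays. The 3 prime minus 5 prime signal of ACTB and GAPDH was 3.89 ± 0.41 (SD, n = 7) in dysplastic nevi, 4.34 ± 1.10 (n = 5) in common nevi and 4.07 ± 0.26 (n = 6) in normal skin. Two-sided exact permutation tests gave p = 0.380 for dysplastic against common nevi (adjusted 0.570), p = 0.701 for common nevi against normal skin (adjusted 0.701) and p = 0.368 for dysplastic nevi against normal skin (adjusted 0.570). Among the nevi the ratio ran from 4.21 to 6.15 on arrays with higher title numbers and from 3.42 to 3.98 on the others. Common nevus replicate 4 had the highest ratio at 6.15, and it also had the lowest eccrine list mean of its group, 5.59. Without it the ratio differed by -0.0011 between dysplastic and common nevi and by -0.18 between common nevi and normal skin.

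**Figure D4:**
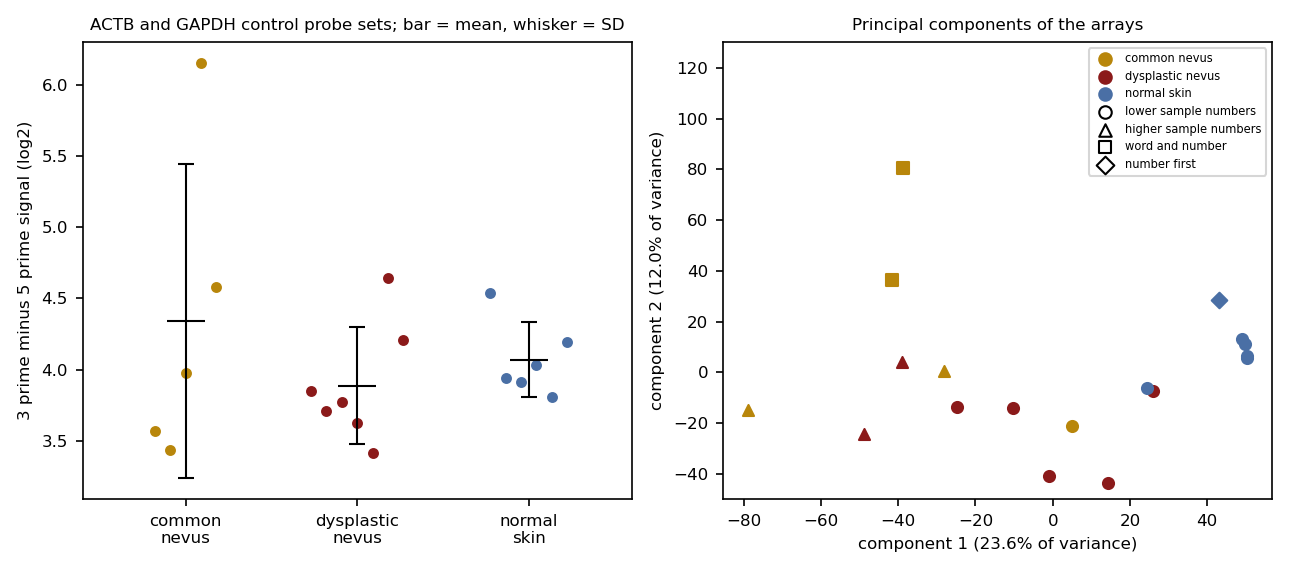
Left, the 3 prime minus 5 prime signal per array (log2) with group means and SD, where common nevus replicate 4 stands at 6.15; right, arrays on the first 2 principal components, coloured by group, with symbols for the range of the sample number in the title. Component 1 holds 23.6% and component 2 holds 12% of the variance.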

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

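The tests of explanations for the 3 patterns below were all chosen after the results they measure had been seen, and the counts of other splits were planned before the data were examined.

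Inner root sheath genes were high on part of the dysplastic nevus arrays: TCHH exceeded log2 5 on 5 of 7 of them and on 0 of the 11 others. Keratin and keratin-associated genes of the hair cortex and cuticle, from other layers of the same follicle, were above log2 5 (at least 3 of 9 genes) on 4 of these 5 arrays and on no other, so the layers matched on 17 of 18 arrays. Each array without TCHH above log2 5 had 1 of the 9 genes above it. A growing hair follicle in the sampled tissue may therefore account for the pattern, and the exception was dysplastic nevus replicate 7, with TCHH at 8.89 and 2 of the 9 genes. Against normal skin 5 of 7 inner root sheath genes were above 0 in dysplastic nevi, and KRT73 went the other way, at -1.46. Fisher's exact test between the nevus groups gave a two-sided p of 0.0278, and 0.722 after multiplication by the 26 lists, so a chance difference in how many samples held such a follicle stays open. A difference between the nevus types themselves was not tested apart from this.

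Activated keratinocyte genes were higher in dysplastic than in common nevi, with a list median of 2.59; the exact permutation p of the list mean was 0.0215, and 0.126 adjusted over the 26 lists. RNA degradation as the whole cause is argued against by a median of 2.39 with the RNA quality ratio as a covariate and 2.17 without common nevus replicate 4. Without common nevus replicates 1, 2 and 4 together the list median was 1.05 and no longer called (adjusted p = 0.0880). Replicates 1 and 2 had the lowest ratios of the common nevi, 3.57 and 3.44, so that loss does not point to degradation. Basal keratinocyte genes had a median of 0.32 and none exceeded 1.23, so as fitted an equal gain of every layer would cover only part of the 2.59. The difference between the nevus types was 2.18 larger in this list than in basal keratinocyte genes (exact permutation p = 0.0290, two-sided), but the p was 0.276 adjusted over the 25 lists compared with basal genes. Given that spread between samples, more epidermis of every layer stays open. The sample series shown by the title numbers cannot be told apart from the nevus types for part of the difference, because the median was 1.51 with the range as a block and 1.75 within the higher numbers, and the lower numbers hold 1 common nevus. A difference between the nevus types stays open and may be biological.

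Matrix genes were lower in common nevi than in normal skin, with a list median of -1.41. The exact permutation p of the list mean was 0.00649, and 0.0422 adjusted over the 26 lists. Dysplastic nevi, also sliced, had a list mean 0.98 above that of common nevi (exact permutation p = 0.00884, two-sided), but 0.115 after adjustment over the 26 lists, so slicing against bulk biopsy stays open. Dilution of all other tissue by nevus cells stays open too: the matrix minus basal keratinocyte mean differed by -1.13 from normal skin (exact permutation p = 0.0130, two-sided, 0.0812 adjusted over the 25 lists), while terminal differentiation (-1.71) and mast cell means (-1.64) differed by no less than the matrix mean (-1.41). All other lists fell by less or rose, among them basal keratinocyte (-0.28), T cell (-0.15), B and plasma cell (0.55) and sebaceous gland means (2.31). Such rises go against an equal dilution of all tissue, but that of the sebaceous list had an exact permutation p of 0.0909 (0.215 adjusted over the 26 lists). The sample series may account for part of the difference, since the median was -0.66 with the range as a block, where camera still called it (adjusted p = 6.11e-05), although in the fit without the block it did not with an estimated correlation (adjusted p = 0.256). A difference in the dermis of common nevi stays open as well.

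Chance could not be excluded for the 1 gene called between the nevus types: 16 of 100 splits of these samples called as many, and the highest other split called 85. The median of the other splits was 0. A split that calls so many more than the real one may point to a structure of the samples other than nevus type, and what that split follows was not tested. Nor could chance be excluded for the number of lists called there, 12 (8 of 100 splits, highest other 17, median 7), or between common nevi and normal skin, 8 (35 of 100, highest other 12, median 7). These counts judge no single list. Exact permutation tests of list means for common nevi against normal skin gave adjusted p = 0.0281 for melanocyte and terminal differentiation genes. They gave 0.0422 for matrix, 0.0450 for ERK, 0.0804 for mast cell and endothelium, 0.0985 for macrophage and 0.215 for sebaceous genes. Between the nevus types the lowest was 0.0657, for growth arrest genes. The permutations ignored the title number ranges. Among splits drawn without regard to these ranges, chance could be excluded for the 874 genes called between common nevi and normal skin (1 of 100, highest other 347). The same held for the 226 genes called between dysplastic nevi and normal skin (2 of 100, with 309 in another split). For the 158 shared genes all group labels were shuffled at once (1 of 100, highest other 1). Such shuffles remove every group difference, so they exclude chance only for the case that no group differs. They do not test chance overlap between sets of real changes. As many as the 12 lists called between dysplastic nevi and normal skin were called in 4 of 100 splits, with 12 in another split and a median of 6, so part of the 12 could arise in any grouping. These splits do not separate group from title number range: with the range as a block the 874 genes became 8, the 226 became 163 and the 158 became 7. The block also leaves fewer arrays to compare, above all common nevi, and how much of these losses is lost precision was not tested.

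Single arrays stood apart from the rest of their group in 26 of 256 groups of values, where chance gives about 1 in 20, or 12.8. The measure is the gap to the nearest array divided by the range of the group. Normal skin replicate 4 accounted for 8: LHX2 was 9.54 against a next value of 2.72 (gap 0.932 of the range), GLDC was 9.06 against 3.85 (0.838), and the sebaceous gland list mean was 8.54 against 5.33 (0.862). On the same array ZIC1 (0.777), PCOLCE2 (0.671), MFAP5 (0.679), PTGIS (0.790) and LOC101927608 (0.850) were the lowest of the group. Common nevus replicate 4 was lowest for ZSWIM3 (0.935) and for the eccrine list mean, 5.59 against 12 (0.840), and highest for ZIC1 (0.760). Common nevus replicate 3 was lowest for HKDC1, 4.81 against 8.82 (0.833), and highest for the macrophage list mean (0.765) and, near the floor, for TCHH (0.920) and KRT27 (0.962). KRT25 on common nevus replicate 1 (0.999), MCHR1 on common nevus replicate 5 (0.837), PRG4 on dysplastic nevus replicate 5 (0.971), GAPDHS on normal skin replicate 1 (a gap of 1, the whole range) and STC2 on dysplastic nevus replicate 4 (1 as well) also lay near the floor. DUSP3 was highest on normal skin replicate 3 (0.822), as was the melanoma-associated list mean (0.628). CCN4 was lowest on dysplastic nevus replicate 1 (0.726), where the T helper cytokine list mean was highest (0.718). GPR143 was lowest on dysplastic nevus replicate 2 (0.587) and the smooth muscle list mean on dysplastic nevus replicate 7 (0.636).

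Probe sets without a single gene symbol entered none of the comparisons above. Of 5097 tested in the same way, limma called 1 between dysplastic and common nevi (1 higher), 126 between common nevi and normal skin (61 higher, 65 lower) and 46 between dysplastic nevi and normal skin (30 higher, 16 lower).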

How the results depend on the processing

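Alternatives that used the title numbers, or left out 3 common nevi together, were chosen after seeing the data, and all others were planned. The 64 named gene results kept their sign in all 2065 alternatives. With title range as a block 19 of 20 named genes of common nevi against normal skin and 9 of 20 of dysplastic nevi lost their call, with fitted differences at a median of 70.1% and 91.6% of their size. Of 1849 planned values of named genes 1662 kept their side of the threshold, 164 no longer passed and 23 newly passed. Of 2340 planned values of gene lists 2102 stayed within the criteria, 84 lost a call, 43 gained one, 111 uncalled medians changed sign and 0 called ones did. Where the values below moved, the cause was not tested.

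Between dysplastic and common nevi, where 1 gene was called, the count was 2 with no filter, 0 with a stricter filter, 6 over every probe set, 4 with the probe set of largest interquartile range, 0 with only these groups fitted, 2 with array weights, 110 at an adjusted p below 0.25 with a 2-fold change, 0 with the RNA quality covariate and 6 without the 2 common nevi titled in another way. It was 2 with title range as a block, 5 within the lower numbers, 9 within the higher numbers and 2 without 3 common nevi. Leaving out 1 array gave 0 to 68, the highest without common nevus replicate 3.

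Between common nevi and normal skin, where 874 genes were called, the count was 549 with no filter, 533 with only these groups fitted, 1381 at the looser threshold and 329 without the 2 common nevi titled in another way. It was 8 with the block, 5 within the lower numbers and 52 without 3 common nevi. Leaving out 1 array gave 466 (without normal skin replicate 3) to 1535 (without common nevus replicate 3). Between dysplastic nevi and normal skin, where 226 were called, the count was 410 with only these groups fitted, 922 with array weights, 694 at the looser threshold, 432 with the covariate, 120 within the lower numbers and 420 without 3 common nevi, and 134 to 339 with 1 array left out. The 158 shared genes became 279 with array weights, 448 at the looser threshold, 7 with the block, 1 within the lower numbers and 25 without 3 common nevi, and 102 to 219 with 1 array left out.

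The RNA quality difference of -0.18 between dysplastic nevi and normal skin was 0.026 from GAPDH alone, -0.39 from ACTB alone and -0.18 from the 3 prime minus middle difference (exact permutation p = 0.918, 0.0752 and 0.0711), and ran from -0.31 to -0.089 with 1 array left out. That of -0.45 between dysplastic and common nevi ran from -0.68 to -0.0011, the last without common nevus replicate 4. That of 0.27 between common nevi and normal skin ran from -0.18 (without common nevus replicate 4) to 0.50 with 1 array left out.

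List medians that were called in either fit and changed sign did so in the added alternatives. Basal keratinocyte genes between the nevus types went to -0.039 with the block, -0.19 within the lower numbers and -0.0084 without 3 common nevi. Mast cell genes went to -0.33 within the lower numbers and -0.020 without 3 common nevi, and eccrine genes to -0.15 without 3 common nevi. Against normal skin, common nevi gave 0.0020 (block) and 0.086 (lower numbers) for macrophage genes, 0.15 for mast cell genes (lower numbers) and 0.78 for hair cortex genes (block). Signal over background limits all values near the floor, which held 34.9% of the values. Within the lower numbers the 1 common nevus is assumed to vary like the other groups.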

Other observations

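A few genes outside the fixed lists are given here, chosen after their values were seen, and they stand for no group. SERPINE2, a secreted protease inhibitor, rose by 3.86 in common (SE 0.54, adjusted p = 8.13e-04, n = 5) and 3.45 in dysplastic nevi (SE 0.50, adjusted p = 0.00127, n = 7) against normal skin (n = 6). QPCT, glutaminyl cyclase, rose by 1.71 (SE 0.42) and 1.95 (SE 0.38), and the lipid carrier APOE by 0.64 (SE 0.16) and 0.76 (SE 0.15). ERBB3, a neuregulin receptor, rose by 0.81 in dysplastic nevi (SE 0.20, adjusted p = 0.0429) and was 0.70 higher in common nevi (SE 0.21, adjusted p = 0.0560).

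The transcription factor genes EMX2, TBX15 and HOXD10 were likewise chosen after their values were seen, and each passed in 1 nevus type only. EMX2 fell by 2.46 in common nevi (SE 0.52, adjusted p = 0.0113) and TBX15 by 1.40 (SE 0.32, adjusted p = 0.0186), whereas in dysplastic nevi they were at -1.52 (SE 0.47, adjusted p = 0.101) and -0.33 (SE 0.30, adjusted p = 0.603). HOXD10 fell by 1.84 in dysplastic nevi (SE 0.45, adjusted p = 0.0445) and was at -0.39 in common nevi (SE 0.49, adjusted p = 0.667). Whether these effects differ between the nevus types was tested by their direct comparison, where none passed: EMX2 0.94 (adjusted p = 0.487), TBX15 1.08 (adjusted p = 0.235) and HOXD10 -1.45 (adjusted p = 0.274).

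Among list genes too rarely measured to be tested, SERPINB4, a protease inhibitor of inflamed epidermis, exceeded log2 3 on 4 dysplastic nevus arrays, up to 12.1, and on 0 others. The collagenase MMP1 did so on 3 dysplastic nevus arrays, up to 8.62. PRAME, a melanoma-associated antigen, did so on 3 dysplastic and 1 common nevus array, up to 6.03.

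The hypothesis that nevus samples fall into series marked by their title numbers was formed and its test chosen after the data had been seen. With group means removed, arrays of the same number range correlated more with each other (mean r = -0.018, 22 pairs) than with arrays of other ranges (-0.12, 44 pairs). The difference of 0.11 had a one-sided exact permutation p of 0.00317 over 630 arrangements within groups, so a shared series may contribute to the spread within groups. Common nevus replicate 3, the only common nevus with a lower number, had a mean r of 0.951 with the dysplastic nevi of that range and 0.943 with normal skin of that range. With the 1 normal skin array titled in another way r was much the same, at 0.9425. Mean r was 0.938 with the dysplastic nevi of higher numbers, 0.919 with the common nevi of higher numbers and 0.915 with the common nevi titled in another way. Each of the last 3 is a mean over 2 arrays, and the common nevi of higher numbers include replicate 4, which had the highest RNA quality ratio (6.15). The RNA quality ratio ran from 4.21 to 6.15 on the nevi of higher numbers and from 3.42 to 3.98 on all other nevi. Among the nevi, higher numbers and RNA quality therefore cannot be told apart. Arrays of a range are not independent replicates of it, and what else the ranges share is not given in the sources used here.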
